A study of Mus musculus with 14 samples.

How the data were processed

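RNA of 11 mouse cell lines was measured on 14 two-colour spotted arrays. Per the labels, each array carried total RNA of 1 line in Cy5 and the Stratagene mouse reference, a commercial pool of RNA from mouse cell lines, in Cy3. No array had the dyes exchanged, so a probe-specific dye effect would enter every ratio alike. The mammary tumor, fibroblast and myeloma lines had 2 arrays each, and the other 8 lines (macrophage, T-cell lymphoma, myoblast, embryo fibroblast, testis, liver, kidney and skin) had 1 each. The labels' titles call the samples cell lines, while their short annotation calls them primary tissue; the titles were followed. The labels do not say that the 2 arrays of a line came from separate cultures, so p-values measure only the spread between arrays, which may be technical. On the first mammary tumor array the reference carried 3 further letters in its label, and whether it was the same pool is not given in the sources used here.

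The deposited values were taken as log2 ratios, 1 per spot and array, as the authors processed them. Background correction, normalization within arrays and spot filters are not given in the sources used here. Base and direction are not stated either and were judged from the values. If the lines entered the pool in equal parts, the mean over the lines of the unlogged ratio of line over pool is 1 for each probe. Read as log2 of line over pool, the median of that mean was 1.00 (quartiles 0.867 and 1.16), against 1.20 with the sign turned, 1.07 with natural logs and 1.87 with log10. For the decile of probes that varied most it was 0.923, against 3.11 with the sign turned, 1.18 with natural logs and 6.68 with log10. The values thus settle the sign and exclude log10, but part log2 from natural logs only weakly. Base 2 was assumed, and every fold given rests on it. Whether the arrays had been centred stayed unknown. The median log2 ratio was 0.053 and 0.011 on mammary tumor arrays 1 and 2, -0.102 and -0.046 on fibroblast arrays 1 and 2, and -0.006 and -0.065 on myeloma arrays 1 and 2. It was -0.078 for liver, -0.044 for macrophage, -0.155 for testis, -0.069 for myoblast, -0.508 for embryo fibroblast, 0.124 for skin, -0.002 for T-cell lymphoma and -0.406 for kidney.

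The value table held 7680 probes, and 423 of its 107520 cells (0.393%) were empty. The 80 spots of Gapdh were averaged, which left 7601 features. The 7423 features with a value in all 11 lines were tested, and 7282 of these were measured on all 14 arrays. The platform annotation listed 6839 probes, of which 6835 had 1 gene symbol and 4 had several; these 4 and 841 unlisted probes were left unnamed. Current symbols were matched through gene identifiers to a RefSeq table of the GRCm38.p6 assembly for 6809 probes, and the others kept the annotation's symbol. The genome build behind the array is not given in the sources used here, so no coordinates are given. Different probes of a gene were tested separately, and averaged where genes rather than probes are counted (6408 tested genes). All columns of the value table were used.

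Tests were run with limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Each line was compared with the equal-weight mean of the other 10 lines in 1 fit over all 14 arrays (lmFit and eBayes, two-sided), in which the reference cancels as far as it was the same on every array. The 3 lines with 2 arrays gave 3 residual degrees of freedom, to which the moderation added 3.75, with a median residual SD of 0.430 on the log2 scale. A lone array was assumed to vary like these pairs. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its line. The number of arrays limits the precision of all of these values. Errors given after a difference are standard errors of the fit.

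A probe was termed unique to a line when the mean of that line's arrays was at least 2 on the log2 scale (4-fold over the pool) and every other measured line was at or below 0, over the 7600 features measured in at least 8 lines. A transcript made by 1 of 11 lines pooled in equal parts would be 11-fold, or 3.46 on the log2 scale, above the pool in that line. Lineages were compared on line means with the line as replicate: the 3 blood-cell lines (macrophage, myeloma, T-cell lymphoma) with the other 8, and the 3 mesenchymal lines (fibroblast, embryo fibroblast, myoblast) with the 5 lines named for an organ.

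Gene lists were written from textbook knowledge: epithelial, mammary gland, liver, macrophage, extracellular matrix and fibroblast, muscle, B and plasma cell, T cell, pan-leukocyte, melanocyte, keratinocyte, testis somatic, germ cell and pluripotency, kidney, endothelial, cell cycle, cytosolic ribosomal protein, interferon response, cholesterol synthesis, oxidative phosphorylation, histone and glycolysis genes. Of 936 list entries 933 matched a gene of the RefSeq table by its current or an older symbol. Fewer were among the tested genes, and the size given for a list counts only its tested genes. Some genes stand in more than 1 list. Each list was tested with limma's cameraPR on the moderated statistics of the 6408 tested genes, with a preset correlation between genes of 0.01. Adjustment ran over the 242 tests of 22 lists in 11 lines, and within each lineage comparison over its 22 tests. The same tests were repeated with a correlation estimated from the arrays.

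The named genes followed a rule. For each line they are the 8 called genes with the largest positive and the 4 with the largest negative difference, up to 4 members of the line's own list, and the 5 unique genes with the widest gap to the next line. For each lineage comparison they are the 14 most positive and the 8 most negative called genes. Sequence tags and genes of no assigned function could be left out. A difference given for a gene named by this rule is that of its probe with the widest difference, unless another probe is mentioned. For other members of the lists it is the mean over the gene's probes. Groups, tests, lists, this rule and the first set of other settings were fixed before the data were examined.

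The fits were tested on simulated data with the real array numbers, with 50 changed probes for each size among 7423. Noise was drawn independently for each value, with a spread taken from the data for each probe and no drift along the probe number. A lone array thus varied like the pairs by construction, so the shares do not test that assumption. For the macrophage line (1 array) 0%, 52.0%, 90.0% and 98.0% of probes changed by 1, 2, 3 and 4 on the log2 scale were called, with 12 unchanged probes called. For the myeloma line (2 arrays) the shares were 6.0%, 94.0%, 100% and 100%, with 9 unchanged probes. For the blood-cell lines they were 12.0%, 52.0%, 88.0% and 98.0%, with 2, and for the mesenchymal lines 4.0%, 64.0%, 86.0% and 90.0%, with 10.

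The first set of other settings comprised other filters on missing values, median centring, quantile normalization, the run of image numbers in the labels as a random block, a fold threshold, genes in place of probes, a robust prior, other limits for unique probes, a weight of 2 for lines with 2 arrays, other settings of the list test, and leaving out each array of a pair or each line in turn. Removal of a running median over 101 probes in order of probe number, probes with a gene name only, and other treatments of the fibroblast arrays were added after the data were seen.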

Results

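Universal Mouse Reference RNA is a commercial pool used as the common channel of two-colour arrays. The series title asks which genes single cell lines contribute to it. Log2 ratios of line over pool were measured for 11 lines on 14 arrays, with 2 arrays for the mammary tumor, fibroblast and myeloma lines and 1 for each other line. For lines with 1 array the line's own value has no replicate check, and n = 1 applies wherever a single value is given.

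The mammary tumor and myeloma pairs correlated more than any arrays of different lines, and the fibroblast pair did not. Across probes, which are not independent replicates, Pearson's r was 0.665 between the mammary tumor arrays, 0.676 between the myeloma arrays and 0.379 between the fibroblast arrays. The SD of the difference between the arrays of a pair was 0.552 and 0.792 on the log2 scale for the first pairs and 1.003 for the fibroblast pair. Over the 88 pairs of arrays of different lines the mean r was 0.196, with a range from -0.142 to 0.487, the highest for fibroblast array 1 with the skin line. The mean was 0.193 over 21 such pairs within a run of image numbers and 0.197 over 67 pairs across runs. These means mix lines of like and unlike lineage, so they do not exclude an effect of the run. With the run as a random block, the correlation that limma estimated between arrays of a run was 0.470. The myeloma arrays shared a run, while the mammary tumor arrays did not, nor did the fibroblast arrays. The spread of the myeloma pair thus holds no difference between runs.

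In the fit as described the 3 blood-cell lines had the most calls, an order that other settings change. With quantile normalization the mammary tumor line had 328, the macrophage line 113 and the T-cell lymphoma line 76, and without myeloma array 2 the myeloma line had 41. In the 11 comparisons of a line with the other 10, 1545 calls were made among 7423 tested probes: 497 in the myeloma line, 340 in the T-cell lymphoma line, 302 in the macrophage line, 164 in the embryo fibroblast line, 91 in the fibroblast line, 64 in the mammary tumor line, 59 in the myoblast line, 26 in the testis line, 1 each in the liver and kidney lines and 0 in the skin line. Whole arrays were shifted as well. The median difference over all tested probes was -0.42 in the embryo fibroblast line, -0.27 in the kidney line, 0.25 in the skin line, 0.19 in the mammary tumor line, 0.12 in the T-cell lymphoma line and 0.11 in the myeloma line. With each array centred on its median these shifts were 0.02, 0.05, -0.01, 0.03, -0.00 and 0.02. Single differences are to be read against the shift of their line. The arrays also differed in spread. The SD of their log2 ratios was 1.16 for T-cell lymphoma, 1.14 for macrophage and 0.993 and 0.978 for myeloma. It was 0.955 for kidney, with 1 call, 0.787 for testis, 0.782 for skin, 0.766 for liver and 0.727 and 0.637 for mammary tumor. All lines share 1 residual variance per probe, so a wider array can gain calls. Whether the spread came from the arrays or the RNA was not tested.

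**Figure D1:**
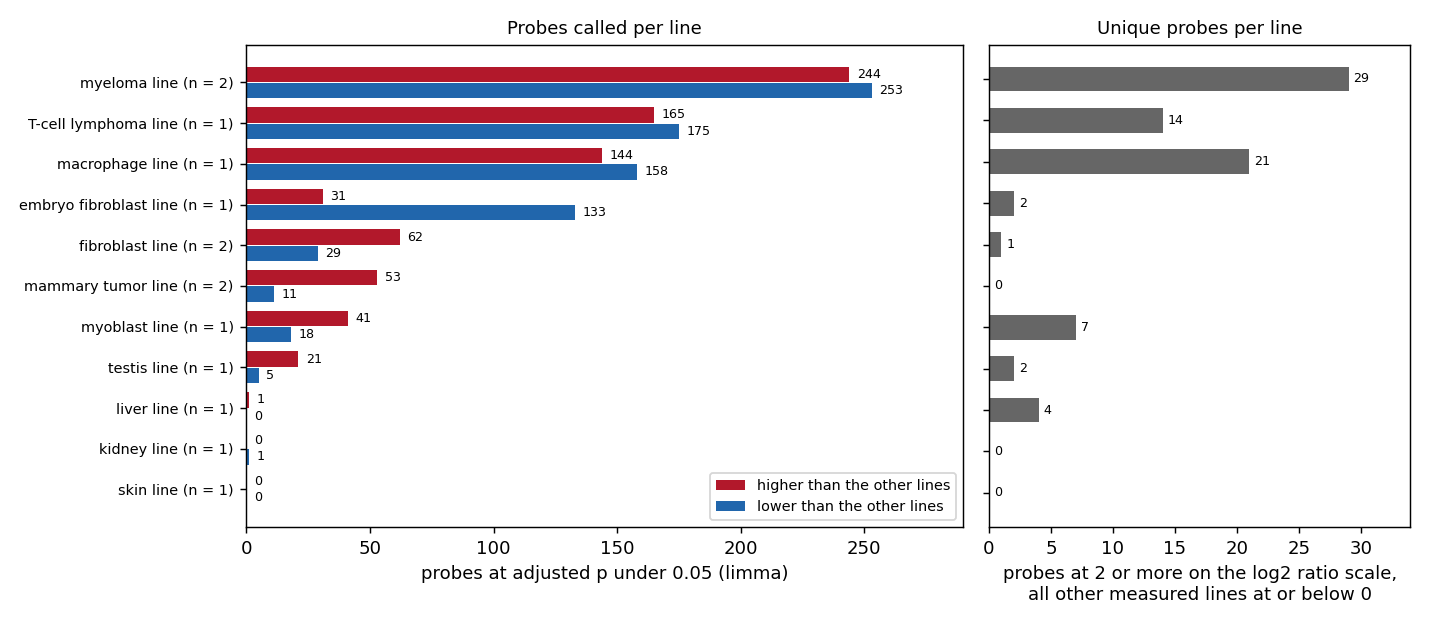
Bars on the left count probes higher (red) or lower (blue) in a line than the mean of the other 10 lines at adjusted p under 0.05 (limma), and bars on the right count probes unique to a line; n is the number of arrays per line. The myeloma line had the most calls, 244 higher and 253 lower, and the most unique probes, 29.

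In the macrophage line Cd36, a scavenger receptor for oxidized lipoproteins, had a log2 ratio of 3.83 against a mean of -2.93 in the other lines, a difference of 6.76 ± 1.11 (109-fold, limma adjusted p = 0.0257). Gpnmb, a membrane glycoprotein of macrophages and pigment cells, was higher by 6.71 ± 0.49 (105-fold, adjusted p = 0.00761), Plek (pleckstrin) by 5.89 ± 0.47 and the chemokine gene Ccl24 by 5.89 ± 0.74. Differences of the lysosomal genes Laptm5 and Cd68 were 5.41 and 5.27, that of the GTPase gene Rac2 was 5.08, that of Alox5ap, which serves leukotriene synthesis, was 5.06, and that of the lipopolysaccharide co-receptor gene Cd14 was 4.47. Lower genes were Loxl1, a collagen and elastin cross-linking enzyme (-5.82 ± 0.77), Nedd4, a ubiquitin ligase (-5.80 ± 0.42), Thbs1 (thrombospondin 1, -5.76 ± 0.54) and Htra1, a secreted protease (-5.25 ± 0.86, adjusted p = 0.0257, which became 0.0691 with quantile normalization).

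Of 48 macrophage genes 18 were higher in the macrophage line and 0 lower over all genes, and 26 were higher adjusted over the list alone, among them Adgre1 (4.39) and Lyz1 (3.77). The list rose (limma cameraPR adjusted p = 2.56e-24; adjusted p = 0.428 with an estimated correlation). Interferon response genes rose too, with 7 of 23 higher (16 adjusted over the list alone), among them Ifit3 (4.05) and Isg15 (3.57), at adjusted p = 1.86e-12 and adjusted p = 0.428 with an estimated correlation. Extracellular matrix and fibroblast genes fell, with 18 of 63 lower (30 lower and 1 higher adjusted over the list alone) and adjusted p = 1.31e-15 (adjusted p = 0.442 with an estimated correlation). None of the 57 list calls over the 11 lines held at 0.05 with a correlation estimated from the 3 residual degrees of freedom. In total 144 probes were higher and 158 lower in the macrophage line, and quantile normalization gave 77 higher and 36 lower. The count was 145 or 134 without mammary tumor array 1 or 2, and 195 without myeloma array 1.

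The myeloma line carried genes of B-lymphocyte and plasma cell identity. Gas6, a ligand of the TAM receptor tyrosine kinases, showed the widest difference of the named genes, with log2 ratios of 2.10 and 3.09 on the 2 arrays against a mean of -5.54 in the other lines (8.14 ± 0.42, 283-fold, limma adjusted p = 0.00132). Irf4, a transcription factor needed for plasma cells, was higher by 5.67 ± 0.61 and the adaptor gene Blnk by 5.31 ± 0.33. The adhesion molecule gene Cntn3 (5.34 ± 0.38) and Cytip, a regulator of leukocyte adhesion (4.88 ± 0.32), followed. Differences of the coactivator gene Pou2af1, the sialyltransferase gene St6gal1, the chemokine receptor gene Cxcr4 and Tnfrsf13b, which encodes the receptor TACI, were 4.91, 4.99, 4.88 and 4.63. Of the other probes of St6gal1 one was called (3.09) and one was not (0.71). Xbp1, the transcription factor of the secretory stress response, was higher by 3.32 ± 0.32. The calcium-binding protein genes S100a6 and S100a4 were lower (-7.12 ± 0.32 and -4.89 ± 0.36), as were the galectin gene Lgals1 (-6.17 ± 0.36) and Emp1 (-5.13 ± 0.75).

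Of 19 B and plasma cell genes 11 were higher in the myeloma line and 0 lower, and 11 adjusted over the list alone. They included Prdm1 (2.60), Ms4a1 (3.29) and Sdc1 (2.21). The list rose at adjusted p = 7.59e-15 (limma cameraPR; adjusted p = 0.428 with an estimated correlation). Of 27 epithelial genes 4 were higher and 1 lower (7 and 2 adjusted over the list alone), at adjusted p = 0.0121, adjusted p = 0.497 with an estimated correlation and adjusted p = 0.147 on ranks. Those higher were Epcam (4.55), the serine protease inhibitor gene Spint2 (4.35), the transcription factor gene Elf3 (4.07) and the claudin gene Cldn7 (4.03), and the lower was the integrin gene Itga6 (-1.75). All but Epcam were picked after their values were seen. Matrix genes fell, with 24 of 63 lower (33 adjusted over the list alone), at adjusted p = 1.11e-18 and adjusted p = 0.428 with an estimated correlation. The counts over all probes were 244 higher and 253 lower. They summed to 497, to 222 without myeloma array 1, 41 without myeloma array 2, and 286 or 268 without mammary tumor array 1 or 2. Without myeloma array 2 the adjusted p was 0.0762 for Irf4, 0.0661 for Xbp1, 0.0655 for St6gal1, 0.0642 for Epcam and 0.0569 for Emp1, and without either myeloma array Cxcr4 was not called.

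In the T-cell lymphoma line Lat, the adaptor that links the T-cell receptor to its effectors, had a log2 ratio of 2.12 against -2.72 in the other lines, a difference of 4.84 ± 0.41 (28.6-fold, limma adjusted p = 0.0114). The kinase gene Zap70 was higher by 4.22 ± 0.40, the receptor chain gene Cd3g by 4.09 ± 0.48 and the transcription factor gene Lef1 by 3.90 ± 0.34. Outside that list, Esm1 (endocan) was higher by 5.76 ± 0.85, the kinesin gene Kif7 by 5.72 ± 0.48, Ptprc, which encodes CD45, by 5.64 ± 0.79, the glucose transporter gene Slc2a3 by 5.08 ± 0.40, the actin regulator gene Coro1a by 4.88 ± 0.48 and Emb (embigin) by 4.60 ± 0.45. The log2 ratios of Esm1 (4.159) and Kif7 (6.105) lay above 3.46, the level of a gene made by a single line in a pool of equal parts. Perp, a desmosomal membrane protein gene, was higher by 4.65 ± 0.97 with an adjusted p of 0.0486, and was no longer called in 8 of 17 other settings. The lysosomal genes Cd63 (-5.66 ± 0.56) and Ctsl (32.0-fold), Anxa3 (-4.93 ± 0.49) and the protease inhibitor gene Timp2 (-4.59 ± 0.73, adjusted p = 0.0880 with quantile normalization) were lower.

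Of 35 T cell genes 7 were higher in the T-cell lymphoma line and 0 lower over all genes, among them Bcl11b (3.29) and Thy1 (3.65). Adjusted over the list alone 9 were higher and 2 lower, the receptor genes Notch1 (-1.65) and Notch3 (-2.20), named after their values were seen. The list rose at adjusted p = 4.84e-05 (limma cameraPR; adjusted p = 0.428 with an estimated correlation), but its median of 0.39 did not pass against random lists of the same size (adjusted p = 0.233). Matrix genes fell, with 19 of 63 lower and 1 higher (36 and 1 adjusted over the list alone), at adjusted p = 7.57e-18 and adjusted p = 0.428 with an estimated correlation. The higher gene was Thy1, which is also a thymocyte marker. All probes gave 165 higher and 175 lower. The sum of 340 became 762 or 613 without fibroblast array 1 or 2, 130 or 108 without mammary tumor array 1 or 2, 214 or 201 without myeloma array 1 or 2, and 76 with quantile normalization.

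In the myoblast line the noncoding imprinted RNA gene H19 had a log2 ratio of 3.42 against -3.86 in the other lines, a difference of 7.27 ± 0.46 (155-fold, limma adjusted p = 0.00497). The smooth muscle actin-binding gene Tagln was higher by 6.14 ± 0.38, the gelatinase gene Mmp9 by 5.72 ± 0.47 and Bves, a membrane protein gene of striated muscle, by 4.89 ± 0.41. The secreted and basement membrane genes Fstl1 and Nid2 were higher by 5.11 ± 0.61 and 4.74 ± 0.56, the imprinted gene Peg3 by 4.39 ± 0.57 and the chemokine gene Ccl7 by 4.36 ± 0.46. Peg3 had an adjusted p of 0.0641 after the trend along the probe number was removed, and its other probe was not called (2.19, adjusted p = 0.0993). The call of Ptprd ended in 8 of 17 other settings, removal of that trend included, and that of Jag1 in 7 of 14. Lower genes were the kinase gene Cdkl2 (-4.78 ± 0.66), the phosphatase genes Inpp5d (-4.68 ± 0.62) and Ptprd (-3.79 ± 0.58), and the Notch ligand gene Jag1 (-3.83 ± 0.50). Of the muscle list, 4 genes with wide differences did not pass the test: Des (desmin) differed by 5.80 ± 1.19 (adjusted p = 0.0941), the acetylcholine receptor gene Chrna1 by 5.19 (0.0834), the troponin gene Tnni1 by 4.98 ± 1.04 (0.0977) and Myog (myogenin) by 4.36 ± 1.31 (0.193).

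Of 43 muscle genes 9 were higher in the myoblast line and 0 lower over all genes, and 22 adjusted over the list alone. Itga7 (4.35), Tnnt1 (4.27), Cdh15 (4.25) and Acta1 (4.22) were among them. The list rose at adjusted p = 2.09e-21 (limma cameraPR; adjusted p = 0.428 with an estimated correlation). Matrix genes rose, with 8 of 63 higher (30 higher and 2 lower adjusted over the list alone), at adjusted p = 1.74e-20 and adjusted p = 0.428 with an estimated correlation. The mean of the other lines includes the blood-cell lines, where this list was lower. All probes gave 41 higher and 18 lower, and quantile normalization 26 higher and 20 lower. The sum of 59 became 99 or 132 without fibroblast array 1 or 2, 4 without either mammary tumor array, 3 without either myeloma array, and 5 with the image run as a block. H19, Tagln and Mmp9 were called in all 17 other settings.

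In the fibroblast line Dcn (decorin) had log2 ratios of 2.02 and 1.84 on the 2 arrays against -3.53 in the other lines (5.45 ± 0.35, 43.8-fold, limma adjusted p = 0.00461). The retinoic acid binding protein gene Crabp1 was higher by 5.05 ± 0.35, the BMP antagonist gene Grem1 by 4.51 ± 0.42, the matricellular gene Ccn3 by 4.10 ± 0.33 and the chromatin protein gene Hmga2 by 3.98 ± 0.31. The pyrophosphate transporter gene Ank and the secreted glycoprotein gene Fstl1 were higher by 3.59 ± 0.36 and 3.52 ± 0.45. Thbs2 (thrombospondin 2) was 0.94 on array 1 and 3.40 on array 2 (5.78 ± 0.92, adjusted p = 0.0479), and the haemoglobin gene Hba-a1 4.64 and 2.42 (4.16 ± 0.59, adjusted p = 0.0324). Each call ended in 6 of 15 other settings. The value of 4.64 for Hba-a1 lay above 3.46, the level of a gene made by a single line in a pool of equal parts. Plp2 (-4.87 ± 0.33), Ly6e (-3.74 ± 0.37), the protease inhibitor gene Timp3 (-2.93 ± 0.34) and the G-protein subunit gene Gng2 (-2.79 ± 0.30) were lower.

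Of 63 extracellular matrix and fibroblast genes 11 were higher in the fibroblast line and 1, Timp3, lower. Adjusted over the list alone 25 were higher and 9 lower. The list rose at adjusted p = 1.23e-10 (limma cameraPR; adjusted p = 0.556 with an estimated correlation). The pair of arrays agreed less than the other pairs. The 91 calls, 62 higher and 29 lower, became 16 without fibroblast array 1, 0 without fibroblast array 2, 36 or 35 without mammary tumor array 1 or 2, 22 without myeloma array 2, and 227 with the image run as a block.

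The embryo fibroblast line shared high Crabp1 (4.46 ± 0.47) and Hmga2 (3.44 ± 0.42) with the fibroblast line, where both were also called. Ngef, a guanine nucleotide exchange factor gene, was higher by 4.73 ± 0.60 (26.6-fold, limma adjusted p = 0.0197), the G-protein regulator gene Rgs2 by 4.22 ± 0.59 and Dlk1, a Notch-family membrane protein gene of immature cells, by 4.01 ± 0.38. Tnfrsf11b (osteoprotegerin), Msln (mesothelin) and the growth factor gene Fgf7 were higher by 3.91, 3.80 and 3.46. Some of these were high elsewhere too. The log2 ratio of Rgs2 was 2.54 here and 2.37 in the macrophage line, and that of Msln 2.14 here and 1.62 in the skin line. Fgf7 was 1.83 here and 0.21 and 1.56 on fibroblast arrays 1 and 2. Ngef was 3.75 here and at most 0.08 (skin line) elsewhere. Tmem176b (-7.02 ± 0.51, 130-fold) and Ppp1r1b, which encodes a phosphatase inhibitor (-5.49 ± 0.36), were lower, as were the small nuclear RNA gene Rnu5g (-5.83 ± 0.61) and Mym (48.3-fold). The log2 ratio of Rnu5g was -6.041 here and at lowest -1.122 (macrophage line) elsewhere. That of Mym was -5.843 here and at lowest -1.449 (kidney line) elsewhere. That of Ppp1r1b was -6.224 here and at lowest -1.599 (macrophage line) elsewhere. Each of these low values rests on a single array, and a fault of the spot was not tested. Of 63 matrix genes 1, Ccn2 (connective tissue growth factor, 3.38 ± 0.49, adjusted p = 0.0273), was higher over all genes, and 12 were higher and 4 lower adjusted over the list alone. Lox differed by 4.02 ± 0.76 (adjusted p = 0.0525), Loxl1 by 3.55 ± 0.77 (0.0694) and Postn (periostin) by -3.36 ± 0.72 (0.0676). The list rose at adjusted p = 1.46e-07 (cameraPR; adjusted p = 0.513 with an estimated correlation). Calls leaned to lower values, with 31 higher and 133 lower, but 44 higher and 56 lower after median centring and 24 and 35 after quantile normalization. The sum of 164 became 272 or 287 without fibroblast array 1 or 2, 34 or 30 without mammary tumor array 1 or 2, and 74 or 69 without myeloma array 1 or 2.

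**Figure D2:**
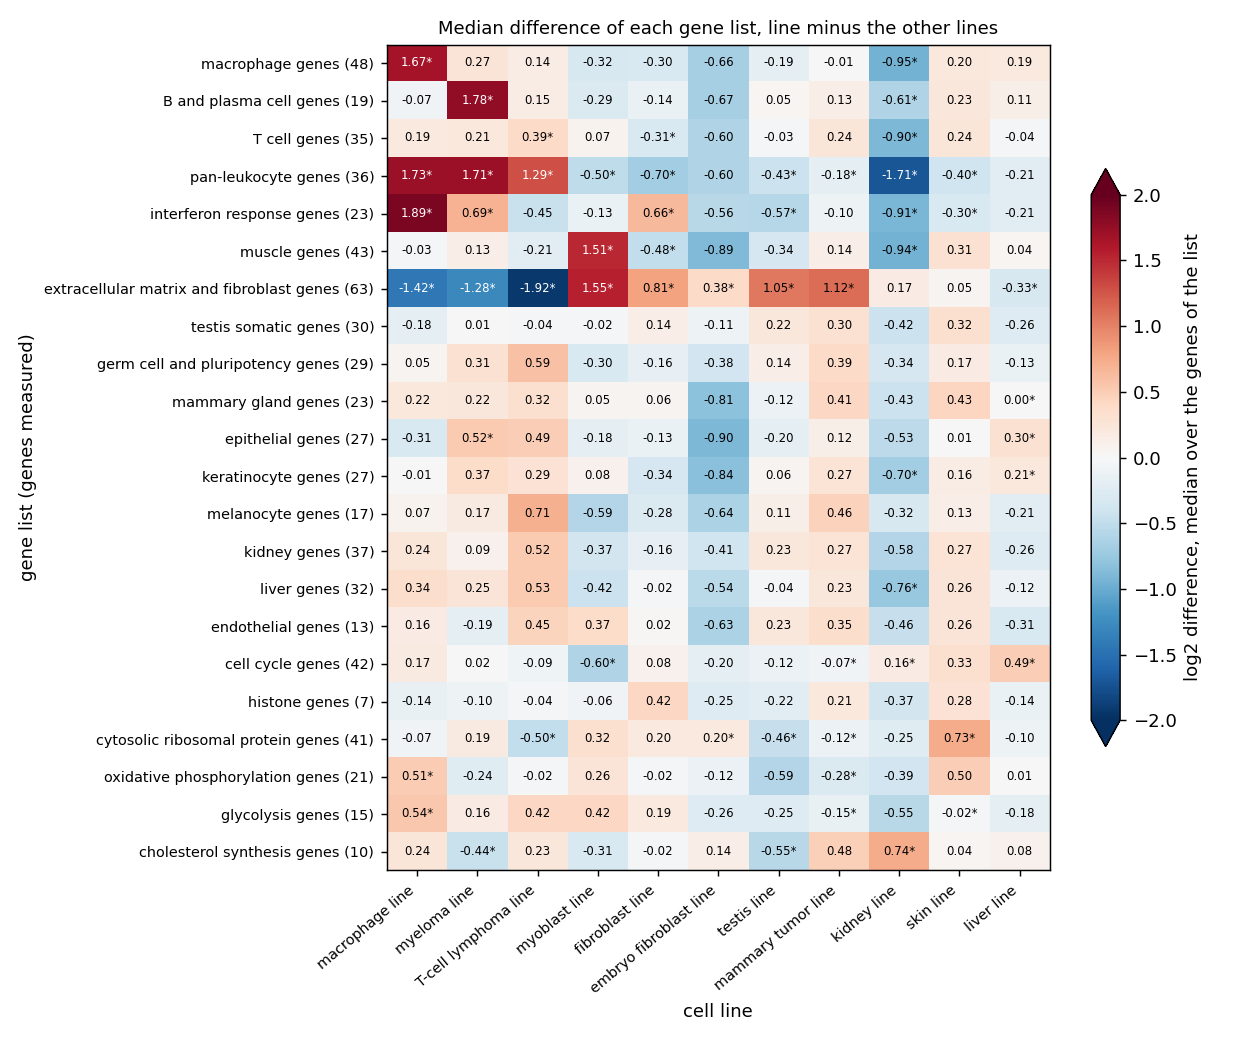
Each cell gives the median over the genes of a list (lines of the grid, with the genes measured) of the log2 difference between a cell line (columns) and the mean of the other lines; colour stops at 2 in either direction and an asterisk marks adjusted p under 0.05 by limma cameraPR, which compares a list with all other genes. Macrophage, B and plasma cell and muscle genes had their highest medians, 1.67, 1.78 and 1.51, in the macrophage, myeloma and myoblast lines.

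In the testis line the transcription factor gene Gata6 was higher by 4.05 ± 0.39 (16.6-fold, limma adjusted p = 0.0402) and Wt1 by 3.89 ± 0.44. These calls ended in 7 and 9 of 17 other settings. The virus receptor and junction protein gene Cxadr was higher by 5.29 ± 0.61 and the matrix protease gene Adamts5 by 4.10 ± 0.34. The call of Cxadr ended in 8 of 14 other settings, the image run as a block included. Each other named call of this line ended in at least 7 of 17. Dcn and Col6a1 were higher by 4.38 ± 0.48 and 4.06 ± 0.50 and the growth factor gene Clec11a by 3.84 ± 0.49. The log2 ratio of Dcn was 0.95 here against 2.02 and 1.84 on fibroblast arrays 1 and 2. That of Col6a1 was 2.27 here against 2.02 and 1.24 there. The aldehyde dehydrogenase gene Aldh1a7 was also called (log2 ratio 2.53, adjusted p = 0.0491). Lower genes were Rpsa, Parvb, Ctps2 and Adgre5, by -2.89 ± 0.33, -2.80 ± 0.35, -2.66 ± 0.34 and -2.63 ± 0.35. The other probe of Rpsa differed by -0.27, and the call ended with genes in place of probes. Of 30 testis somatic genes 2, Gata6 and Wt1, were higher over all genes and adjusted over the list alone, where 1, Rhox5 (-1.62), was lower. The list was not called (cameraPR adjusted p = 0.235). Clu (clusterin) and Trf (transferrin), secreted by Sertoli cells, differed by 2.51 ± 0.84 and 1.78 ± 0.44 and were not called. The other probe of Clu differed by 0.39 and those of Trf by 0.42, 0.40 and 0.22. Of 29 germ cell and pluripotency genes 0 were called by limma over all genes or adjusted over the list alone (list adjusted p = 0.694), with differences of 1.27 ± 0.46 for Sox2 and -0.95 ± 0.51 for the germ cell helicase gene Ddx4. Matrix genes rose, with 4 of 63 higher (18 higher and 1 lower adjusted over the list alone), at adjusted p = 1.82e-12 and adjusted p = 0.497 with an estimated correlation. The 21 higher and 5 lower probes became 35 and 17 after quantile normalization, and 0 in total without fibroblast array 1, either mammary tumor array or either myeloma array. A robust prior gave 4, and Aldh1a7 had an adjusted p of 0.0598 after the trend along the probe number was removed.

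In the mammary tumor line the chemokine gene Cxcl12 had log2 ratios of 2.10 and 2.98 on the 2 arrays against -3.15 in the other lines (5.69 ± 0.47, 51.7-fold, limma adjusted p = 0.014). Ccn5 was higher by 4.82 ± 0.46, the water channel gene Aqp5 by 4.57 ± 0.33, the growth factor binding gene Igfbp4 by 4.48 ± 0.44, Thbs1 by 4.45 ± 0.40, Col5a2 by 4.24 ± 0.55, the cross-linking enzyme gene Lox by 4.06 ± 0.56 and the Wnt antagonist gene Sfrp2 by 3.66 ± 0.26. The neurotrophin receptor gene Ntrk3 (-4.12 ± 0.41), Crip1 (-3.79 ± 0.33), the cyclin gene Ccnd2 (-3.45 ± 0.25) and Dpysl3 (-2.84 ± 0.29) were lower. The other probe of Ntrk3 lay the opposite way and was not called (0.74 ± 0.28, adjusted p = 0.30), and the Ntrk3 call ended with genes in place of probes. Matrix genes rose, with 11 of 63 higher (31 higher and 8 lower adjusted over the list alone), at adjusted p = 1.33e-07 (cameraPR; adjusted p = 0.671 with an estimated correlation).

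Of 27 epithelial genes 0 were called in the mammary tumor line by limma over all genes, and 2 were higher adjusted over the list alone, Perp (3.83 ± 0.71) and the desmosomal gene Pkp1 (1.83 ± 0.31). The list was not called (adjusted p = 0.926), and its median of 0.12 and mean of 0.27 lay above 0 while the test pointed down. The log2 ratio of Krt8 was -3.01. Of 23 mammary gland genes 0 were called over all genes or adjusted over the list alone (list adjusted p = 0.810); Mfge8, a milk fat globule protein gene, differed by 1.93 ± 0.53 (adjusted p = 0.161) and the casein gene Csn3 by -1.17 ± 0.35 (adjusted p = 0.191). The 53 higher and 11 lower probes became 42 and 18 after median centring and 156 and 172 after quantile normalization. The sum of 64 became 114 without fibroblast array 2, 0 without mammary tumor array 1 or 2, 40 or 29 without myeloma array 1 or 2, and 13 with the image run as a block. Of the named genes, Col5a2, Lox and Dpysl3 were not called with that block.

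In the liver line 1 probe was called, that of Krt8, a keratin of simple epithelia. It had a log2 ratio of 2.46 against -3.09 in the other lines, a difference of 5.55 ± 0.42 (46.8-fold, limma adjusted p = 0.0313). Values of Krt19 (5.02 ± 0.63, adjusted p = 0.0982) and the laminin gene Lamb3 (4.19 ± 0.39, adjusted p = 0.0675), picked after they were seen, did not pass the test, nor did that of the protease regulator gene Reck (-5.49 ± 0.58, adjusted p = 0.071). Of 27 epithelial genes 1, Krt8, was higher over all genes and 7 adjusted over the list alone; the list rose at adjusted p = 4.71e-07 (cameraPR; adjusted p = 0.428 with an estimated correlation), as did keratinocyte genes (5 of 27 adjusted over the list alone, adjusted p = 0.0103; adjusted p = 0.497 with an estimated correlation). Against random lists of the same size neither passed (adjusted p = 0.120 and 0.320), nor on ranks (0.0639 and 0.324). Of 32 liver genes 0 were called by limma over all genes or adjusted over the list alone (list adjusted p = 0.238), and the transcription factor gene Foxa2 differed by 1.10 ± 0.45 (adjusted p = 0.602), the growth factor gene Igf2 by -1.54 ± 0.53 (0.483) and the apolipoprotein gene Apoa1 by -1.26 ± 0.88 (0.869). At an unadjusted p under 0.05 there were 608 probes. Quantile normalization gave 8 higher and 4 lower, none was called when any array of a pair was left out, the Krt8 call ended in 9 of 17 other settings, and the adjusted p of Krt8 was 0.0673 after the trend along the probe number was removed.

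In the kidney and skin lines no named gene passed the test. The kidney line had 1 call by limma, an unnamed probe (number 4782) with a log2 ratio of -7.03 against -1.71 (-5.31 ± 0.39, adjusted p = 0.0262), and 1288 probes at an unadjusted p under 0.05; that call was absent without either mammary tumor array or either myeloma array. Wide differences that did not pass, picked after they were seen, were those of Loxl2, a lysyl oxidase (3.66 ± 0.53, adjusted p = 0.0796), Hspb1 (3.60 ± 1.14, adjusted p = 0.205) and the GTPase regulator gene Dlc1 (-4.42 ± 0.74, adjusted p = 0.0877). Of 37 kidney genes 0 were called over all genes or adjusted over the list alone (list adjusted p = 0.481), and Pax8 differed by 1.71 ± 0.83 (adjusted p = 0.342), the inositol oxygenase gene Miox by -1.89 ± 0.52 (0.169) and the collecting duct water channel gene Aqp2 by -1.80 ± 0.72 (0.271). Pan-leukocyte genes fell in the kidney line, 20 of 36 lower and 1 higher adjusted over the list alone and 0 over all genes, at adjusted p = 7.50e-09 and adjusted p = 0.428 with an estimated correlation.

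The skin line had 0 calls by limma and 602 probes at an unadjusted p under 0.05. The fatty acid transport gene Slc27a3 (3.98 ± 0.36, adjusted p = 0.0825) and the fibroblast-line genes Grem1 (3.94 ± 0.58, adjusted p = 0.21) and Hmga2 (3.28 ± 0.42, adjusted p = 0.18) were not called, nor were Lfng, a modifier of Notch receptors (-4.06 ± 0.88, adjusted p = 0.327), and the galectin gene Lgals3 (-3.31 ± 0.44, adjusted p = 0.189). All were picked after they were seen. Of 27 keratinocyte genes 0 were called over all genes or adjusted over the list alone (list adjusted p = 0.762), the closest being the integrin gene Itga6 (1.68 ± 0.35, adjusted p = 0.327). Of 17 melanocyte genes 0 were called in either way (list adjusted p = 0.281). The median of that list was 0.13, its mean -0.01 and the direction of the test down. The pigment cell regulator gene Mitf differed by -1.21 ± 0.54 (adjusted p = 0.643; other probes -1.12 and -0.10) and Pmel by 1.01 ± 0.37 (adjusted p = 0.574).

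By the rule with a minimum of 2, unique probes were most frequent in the blood-cell lines, an order that other limits change. Arrays of these lines also had the widest spread, which fixed limits favour. Of 7600 probes 80 (1.05%) were unique to a line: 29 to the myeloma line, 21 to the macrophage line, 14 to the T-cell lymphoma line, 7 to the myoblast line, 4 to the liver line, 2 each to the embryo fibroblast and testis lines, 1, without a gene name, to the fibroblast line and 0 to the kidney, mammary tumor and skin lines. In the macrophage line the unique genes with the widest gap were Plek (2.51, next line -2.24), Ccl24 (4.21, next -0.16), the costimulatory receptor gene Cd28 (2.97, next -0.88), Alox5ap and Gpnmb. In the myeloma line they were Gas6, Irf4, the olfactory receptor gene Olfr1355, the transcription factor gene Mef2b and the adhesion gene Epcam (2.37, next -0.97). In the T-cell lymphoma line they were Esm1 (4.16, next -0.41), Slc2a3 (2.82, next -1.52), Cd3g, Lat and the cadherin gene Celsr1. The myoblast line had H19 (3.42, next -2.96), Des (3.61, next -0.94), Mmp9, Chrna1 (4.29, next -0.04) and Bves, besides Myog and Mmp3. The liver line had Krt8 (2.46, next -2.12), Krt19 (2.72, next -0.98), Pcbd1, a cofactor recycling enzyme, and Zdhhc2, a palmitoyltransferase. Krt19 and Zdhhc2 have neighbouring probe numbers, 5586 and 5585, and lay close on most arrays. They were -4.106 and -4.785 in the macrophage line and -1.327 and -1.274 in the kidney line, but -1.961 and -4.539 on myeloma array 2. Whether these probes give separate signals was not tested. Dlk1 (2.19, next -1.22) was unique to the embryo fibroblast line, beside an unnamed probe, and Aldh1a7 and Clec11a to the testis line.

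The arrays of a pair gave the rule different results. On myeloma arrays 1 and 2 taken singly 22 and 31 probes were unique, with 19 on both. On the fibroblast arrays there were 0 and 1, with 0 on both, and on the mammary tumor arrays 0 and 1, with 0 on both. The embryo fibroblast line had 1 unique probe without myeloma array 2 and the kidney line 1 without that array, the fibroblast line 0 without fibroblast array 2, and the mammary tumor line 1 without mammary tumor array 1. A minimum of 1 in the line gave 48 unique probes in the T-cell lymphoma line and 41 in the macrophage line, and a minimum of 3 gave 2 and 3, with 0 in the myeloma line and 6, the most of any line, in the myoblast line. With other lines at or below 1 the myoblast line had 48 and the myeloma line 45. Of 105995 values 39 lay above 3.46, the level that a gene made by a single line would reach in a pool of equal parts, 13 of them on the T-cell lymphoma array and 9 on the myoblast array. The highest was Kif7 in the T-cell lymphoma line (6.11). On the other arrays Kif7 lay between -0.643 (kidney line) and 1.169 (macrophage line). A pool of equal parts does not allow such a value, which rests on a single array, and a fault of the spot was not tested. Other values above 3.46 included Hba-a1 on fibroblast array 1 (4.64) and Ccl24 (4.21) and Cd36 (3.83) in the macrophage line. Chrna1 (4.29) and Mmp9 (3.89) in the myoblast line, Ngef (3.75) in the embryo fibroblast line and Slc27a3 (3.75) in the skin line were above it too.

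**Figure D3:**
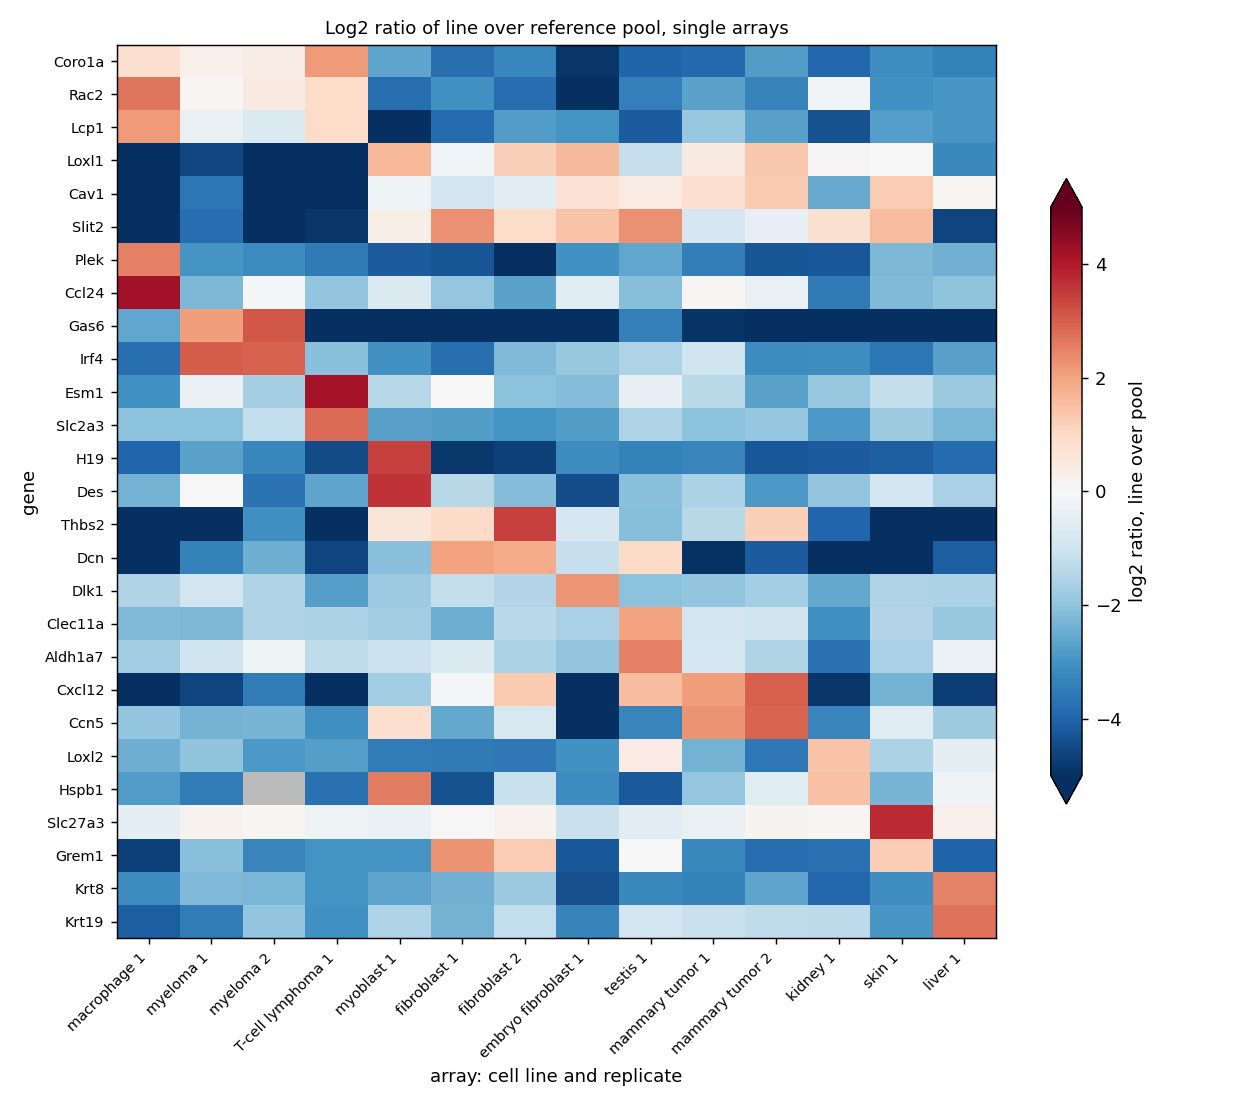
Log2 ratios of line over pool for genes named in the text (vertical axis) on each of the 14 arrays (horizontal axis, line and replicate number); colour stops at 5 in either direction and the grey cell is an empty value. Gas6 was 2.10 and 3.09 on the myeloma arrays against a mean of -5.54 in the other lines.

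In the blood-cell lines the actin regulator gene Coro1a had a mean log2 ratio of 1.07 ± 0.93 (SD, n = 3 lines) against -3.60 ± 0.68 (SD, n = 8), a difference of 4.67 ± 0.47 (25.4-fold, limma adjusted p = 0.000318), with the lowest blood-cell line at 0.30 and the highest other line at -2.63. The GTPase gene Rac2 was higher by 4.42 ± 0.80, the actin-bundling gene Lcp1 by 4.34 ± 0.63, Cytip by 4.24 ± 0.54 and the phosphatase gene Ptpn18 by 4.11 ± 0.48. Differences of Laptm5, Inpp5d, the tetraspanin gene Cd53 and Cxcr4 were 3.95, 3.86, 3.86 and 3.76. The transcription factor gene Fli1, St8sia4, the ion channel gene Trpv2, the adaptor gene Dok3 and Hcls1 were higher by 3.45, 3.28, 3.28, 3.23 and 3.21. Loxl1 (63.9-fold, adjusted p = 0.00207), the caveolin gene Cav1 (-5.42 ± 0.67), the guidance molecule gene Slit2 (-5.39 ± 1.10), Thbs1 (-5.38 ± 0.97), the collagen genes Col5a2 (-5.25 ± 1.17) and Col6a1 (-5.12 ± 1.07), the fascin gene Fscn1 (-4.93 ± 0.57) and Sparc (-4.32 ± 0.53) were lower. The mean of Sparc was -4.07 against 0.24. The calls of Slit2, Col5a2 and Col6a1 ended with quantile normalization and in 3, 6 and 4 of 23 other settings. When a blood-cell line was left out, those of Cxcr4, Dok3 and Fli1 ended in 2 settings each and those of Inpp5d and Laptm5 in 1 each, with adjusted p up to 0.0908, 0.104, 0.0537, 0.0530 and 0.0520. Groups overlapped for 4 of these genes. The lowest blood-cell line was below the highest other line for Laptm5 (-1.62 and -1.36) and Dok3 (-1.52 and -1.04), and in the liver line Slit2 (-4.59) and Col5a2 (-4.78) lay below the highest blood-cell line (-4.43 and -4.68).

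Of 36 pan-leukocyte genes 19 were higher in the blood-cell lines and 1, the thymosin gene Tmsb10, lower (22 and 3 adjusted over the list alone). This list rose at adjusted p = 1.95e-18 (limma cameraPR) and held with an estimated correlation (adjusted p = 0.0156). In the single lines it rose too, with 13 higher in the macrophage line, 18 in the myeloma line and 11 in the T-cell lymphoma line (adjusted p = 8.95e-13, 2.09e-13 and 2.60e-07; adjusted p = 0.428 with an estimated correlation in each), and 20, 20 and 17 higher and 4, 2 and 2 lower adjusted over the list alone. Of 63 matrix genes 21 were lower and 0 higher (32 lower adjusted over the list alone); the list fell at adjusted p = 1.35e-24, with adjusted p = 0.0532 with an estimated correlation. Of 48 macrophage genes 5 were higher (7 adjusted over the list alone), Aif1, Itgb2, Ncf4, Spi1 and Cd53, at adjusted p = 2.81e-06 and adjusted p = 0.536 with an estimated correlation; Itgb2 and Cd53 stand in the pan-leukocyte list too. T cell (adjusted p = 0.00508, with Ikzf1 higher) and B and plasma cell genes (0.0244, with Sdf2l1 higher) rose too. So did lists not named for blood cells: interferon response (0.00556, 0 called), liver (0.0135, 0 called), glycolysis (0.0387, with Pfkp higher) and melanocyte genes (0.0499, 0 called). Each of these 6 lists had adjusted p = 0.536 with an estimated correlation, and adjusted over the list alone 2, 2, 0, 0, 1 and 2 of their genes were higher and 0 lower. These 3 genes were picked after their values were seen. In all 74 probes were higher and 165 lower, 239 in sum, in 224 named genes. Of 100 splits of the lines into 3 and 8 only the real one called as many, and the highest other count was 6. The count was 116 without the T-cell lymphoma line, 146 without the myeloma line, 136 without the fibroblast line and 111 with quantile normalization.

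Between the mesenchymal and the organ-named lines 0 probes were called by limma and 510 had an unadjusted p under 0.05. The smallest adjusted p was 0.411, that of Peg3 (3.82 ± 0.61, mean 1.73 ± 1.12 SD in 3 lines against -2.09 ± 0.96 SD in 5), whose other probe differed by 0.91. Thbs2 (4.25 ± 1.23) and Cxadr (-3.78 ± 1.11) had wide differences and, like Peg3, were picked after their values were seen. Matrix genes rose as a list, with 0 of 63 called over all genes and 1 higher adjusted over the list alone (limma cameraPR adjusted p = 2.23e-11; adjusted p = 0.491 with an estimated correlation). Muscle genes rose too, with 0 of 43 called (adjusted p = 0.00197; adjusted p = 0.851 with an estimated correlation). The rise was not particular to these lists. Cytosolic ribosomal protein and interferon response genes (each adjusted p = 1.30e-04; adjusted p = 0.822 with an estimated correlation) and glycolysis genes (adjusted p = 0.00197; adjusted p = 0.491 with an estimated correlation) rose with 0 called. Melanocyte and cell cycle genes fell with 0 called (adjusted p = 0.0221 and 0.0358; adjusted p = 0.822 and 0.851 with an estimated correlation). Without the myoblast line 1 probe was called.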

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

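A total of 4 genes had 1 line far from the others of its group by Dixon's test, out of 30 groups tested; chance alone marks about 1 in 20. Rac2, a GTPase of blood cells, was -0.16 in the kidney line, and the next of the 8 lines not of blood was at -2.90. Inpp5d, a phosphatase of blood cells, was -6.003 in the myoblast line, and the next of these lines was at -2.996. The guidance molecule gene Slit2 was -4.59 in the liver line, and the next of these lines was at -0.63. Dcn was 0.95 in the testis line, and the next of the 5 organ-named lines was at -4.13. Each of these is a single array, and no explanation was tested for them.

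Of the tests that follow, those of the trend along the probe number in the fibroblast pair, of the Gapdh spots and of the centring of the embryo fibroblast array were chosen only after the result was seen. The fibroblast arrays had the lowest correlation of the 3 pairs, and values on fibroblast array 1 drifted most along the probe number. That drift is not the whole cause, since the correlation was 0.461 after its removal, against 0.681 for the mammary tumor and 0.693 for the myeloma pair. Random spot noise could account for the gap: over 134 genes with 2 probes the difference between the arrays at one probe correlated with that at the other at 0.103, within the range of shuffled pairs (95% limit 0.145, permutation p = 0.115 with 10000 shuffles). The test is weak, because the same measure was 0.193 over 135 genes (permutation p = 0.0115) for the mammary tumor and 0.154 over 137 genes (permutation p = 0.0348) for the myeloma pair, so different RNA on the 2 fibroblast arrays may also be the cause. At 0.103 these causes cannot be told apart.

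Values drifted and jumped along the probe number within arrays, with a trend SD of 0.444 on fibroblast array 1, 0.357 on the T-cell lymphoma array, 0.346 on the embryo fibroblast array, 0.336 on the testis array and 0.318 on the kidney array. The 80 spots of Gapdh, which all measure one RNA, followed the running median of the other probes around them on some arrays, with a median correlation over the 14 arrays of 0.359 and values of 0.630, 0.670, 0.542, 0.738 and 0.591 on those 5 arrays. The correlation was low on the liver (0.143), first myeloma (0.167) and myoblast (0.179) arrays, and negative on fibroblast array 2 (-0.128) and mammary tumor array 2 (-0.320). The same 0.359 argues against genes of like regulation printed next to each other as the whole cause. A position effect is likely part of it on the 5 arrays with the widest drift and stays open for the others, while the design holds no group that gives a biological explanation to test.

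Calls of the embryo fibroblast line leaned to lower values, 31 higher and 133 lower. With each array centred on its median 56% were lower, but centring itself evens the share, so this does not test the cause. The array had a median of -0.508 on the log2 scale; whether that comes from the array or from the RNA of the line stays open.

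For the lineages, the number of calls was compared with that of other splits of the same lines. The blood-cell split called 239 probes, and 1 of 100 splits, the real one, reached that number, with 6 as the highest other count, so an arbitrary grouping of lines is unlikely to be the cause. For the mesenchymal lines the real count was 0, which 56 of 56 splits reach by necessity (highest other 6), so the comparison of splits decides nothing. In both comparisons the split with 6 calls set the fibroblast, embryo fibroblast and skin lines apart. The 0 calls therefore do not show that fibroblast-like lines lack a shared difference.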

How the results depend on the processing

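No paired analysis was possible because the labels number only the second array of 3 lines and do not tie an array of one line to an array of another, and the other 8 lines have 1 array each. The small number of arrays makes the counts imprecise: without an array of a pair 2 residual degrees of freedom are left, and the lone array is assumed to vary like the others. Fewer arrays did not always mean fewer calls, since those of the T-cell lymphoma line rose without either fibroblast array. The signal over background of the spots was not analysed here. The cause of a change was not tested.

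No named gene turned its direction in a setting where it was called there or in the fit as described. Turns of genes called in neither were not counted. Of 110 called genes of the lines 110 stayed called with median centring, 106 with quantile normalization, 97 with the run as a block, 96 with a robust prior, 69 without either mammary tumor array and 74 without myeloma array 2. Of 22 lineage genes 19 stayed called with quantile normalization and 16 without the macrophage line. Of 57 list calls 57 stayed with median centring, 49 with ranks, 46 with random lists, 27 with a preset correlation of 0.05 and 0 with an estimated one. Mammary gland genes in the liver line, called higher at adjusted p = 0.035, reversed against random lists, their median being 5.0e-04. That call ended on ranks too (cameraPR adjusted p = 0.681).

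Leaving out arrays of a pair gave from 30 to 287 called probes in the embryo fibroblast line, 0 to 62 in fibroblast, 0 to 1 in kidney, 0 to 0 in liver, 134 to 421 in macrophage, 0 to 114 in mammary tumor, 41 to 730 in myeloma, 3 to 132 in myoblast, 108 to 762 in T-cell lymphoma and 0 to 27 in testis. Unique probes ranged from 1 to 2 in embryo fibroblast and from 0 to 1 in fibroblast, kidney and mammary tumor. Leaving out arrays or lines gave 116 to 342 probes for the blood-cell lines and 0 to 1 for the mesenchymal lines.

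Quantile normalization gave 76 calls in T-cell lymphoma, 59 in embryo fibroblast, 12 in liver, 113 in macrophage, 328 in mammary tumor, 52 in testis and 111 for the blood-cell lines. Median centring gave 100 in embryo fibroblast, with 4 unique there and 0 in fibroblast. The run as a block gave 227 in fibroblast, 5 in kidney, 3 in liver, 13 in mammary tumor and 5 in myoblast. Genes in place of probes gave 108 in embryo fibroblast and 0 in kidney. In testis probes measured in at least 8 lines gave 5 and a robust prior 4.

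A minimum of 1 in the line gave 48 unique probes in T-cell lymphoma, 5 in embryo fibroblast, 2 in fibroblast, 41 in macrophage, 6 in mammary tumor, 12 in myoblast and 5 in testis. A minimum of 3 gave 2 in T-cell lymphoma, 1 in embryo fibroblast, 0 in fibroblast, liver, myeloma and testis and 3 in macrophage; in myoblast it was 6. Other lines at or below 1 gave 60 in T-cell lymphoma, 8 in embryo fibroblast, 5 in fibroblast, 4 in kidney, 10 in liver, 49 in macrophage, 3 in mammary tumor, 45 in myeloma, 48 in myoblast, 2 in skin and 17 in testis.

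Settings chosen after seeing the data were these. With the trend along the probe number removed there were 578 calls in T-cell lymphoma and 41 in testis, and 4 unique probes in embryo fibroblast, 2 in fibroblast and 4 in testis. Named probes alone gave 0 in kidney. With the fibroblast arrays as 2 lines there were 696 in T-cell lymphoma, 265 in embryo fibroblast, 0 in liver, 102 in mammary tumor, 752 in myeloma, 102 in myoblast and 0 in testis. With both fibroblast arrays left out there were 628 in T-cell lymphoma, 304 in embryo fibroblast, 0 in kidney, 0 in liver, 120 in mammary tumor, 118 in myoblast and 0 in testis.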

Other observations

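Cell cycle genes fell in the myoblast line (median -0.60, adjusted p = 3.32e-05; adjusted p = 0.428 with an estimated correlation), where 1 of 42, the inhibitor gene Cdkn1a (2.80), was higher over all genes and 13 were lower adjusted over the list alone. They rose in the liver line (median 0.49, adjusted p = 8.81e-05; adjusted p = 0.428 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. In the myeloma line the list was not called (adjusted p = 0.935), while Mki67 (1.73), Top2a (1.31), Bub1 (2.07) and Ccnd2 (2.63) were higher and Cdc45 (-2.22), Ccnd1 (-2.78) and Cdkn1a (-1.27) lower, and 4 were higher and 5 lower adjusted over the list alone. Ccnd1 was also lower in the T-cell lymphoma line (-4.37) and Cdc45 in the macrophage line (-3.03). Cytosolic ribosomal protein genes rose in the skin line, 39 of 41 above 0 with a median of 0.73 (adjusted p = 6.32e-05; adjusted p = 0.497 with an estimated correlation) and 0 called. They rose in the embryo fibroblast line too (median 0.20, adjusted p = 0.00120; adjusted p = 0.521 with an estimated correlation; 0 called). They fell in the testis line (median -0.46, adjusted p = 0.00309; adjusted p = 0.611 with an estimated correlation), also with 0 called, in the T-cell lymphoma line (median -0.50, adjusted p = 0.0453; adjusted p = 0.654 with an estimated correlation), with 1 lower, Rplp1 (-2.37), over all genes and adjusted over the list alone, and in the mammary tumor line (median -0.12, adjusted p = 0.0302; adjusted p = 0.626 with an estimated correlation; 0 called).

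Interferon response genes fell in the skin line (median -0.30, adjusted p = 1.57e-04; adjusted p = 0.428 with an estimated correlation; 0 of 23 called), and rose in the fibroblast line with 2 higher, the antiviral genes Oas1a (1.99) and Ifit3 (1.48), and 8 higher and 1 lower adjusted over the list alone (adjusted p = 2.02e-04; adjusted p = 0.428 with an estimated correlation). Cholesterol synthesis genes fell in the myeloma line, with Sqle (-2.11) and Cyp51 (-1.41) lower of 10 and 4 adjusted over the list alone (adjusted p = 0.0162; adjusted p = 0.428 with an estimated correlation). Oxidative phosphorylation genes rose in the macrophage line (median 0.51, 0 of 21 called, adjusted p = 0.00991; adjusted p = 0.428 with an estimated correlation). Glycolysis genes rose there with 2 of 15 higher, the lactate transporter gene Slc16a3 (3.43) and Pfkp (2.12) (adjusted p = 0.0339; adjusted p = 0.706 with an estimated correlation). Endothelial genes (13, smallest adjusted p 0.430) and histone genes (7, smallest adjusted p 0.343) were called as lists in no line. Of the histone genes H3c7 was higher in the T-cell lymphoma line (2.70 ± 0.46) and H3f3b lower in the myeloma line (-1.93 ± 0.30). Of the endothelial genes Pecam1 was higher (3.67 ± 0.41) and Eng lower (-2.43 ± 0.29) in the myeloma line, and Eng higher in the macrophage line (2.34 ± 0.40). Against random lists of the same size the calls of cholesterol synthesis genes in the myeloma line and of oxidative phosphorylation and glycolysis genes in the macrophage line ended (adjusted p = 0.118, 0.0593 and 0.0842). All genes named for these lists and for the cell cycle and ribosomal protein lists were picked after their values were seen.

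The other list calls of single lines were these, each with an adjusted p of at least 0.428 with an estimated correlation. In the kidney line macrophage (adjusted p = 2.67e-08), T cell (0.00110), muscle (0.00251), interferon response (0.00309), liver (0.0131), B and plasma cell (0.0399) and keratinocyte genes (0.0471) fell. Cholesterol synthesis (0.0162) and cell cycle genes (0.0350) rose there, and 0 genes were called over all genes in any of these lists. Counts adjusted over the list alone are left out for the calls listed here. Pan-leukocyte genes fell in the skin (3.05e-04), mammary tumor (0.00229), fibroblast (0.00433), myoblast (0.00439, with Inpp5d, Lcp1 and Itgb7 lower) and testis lines (0.0105). In the fibroblast line the only gene called over all genes, the integrin gene Itgb7, went the other way (2.30). These falls are not separate traits of the lines, since each is measured against a mean that includes the blood-cell lines, where this list was higher. Rises of matrix genes in the myoblast, fibroblast, embryo fibroblast, testis and mammary tumor lines share this limit. In the blood-cell lines the matrix list was lower. Interferon response genes fell in the testis line (0.00782) and rose in the myeloma line (0.0239, with Psmb8, Psmb9 and Isg20 higher), and cholesterol synthesis genes fell in the testis line (0.0394). In the fibroblast line muscle genes fell (2.02e-04, with Ankrd1 and Mef2c lower), as did T cell genes (0.0420), and in the liver line matrix genes fell (0.0162). In the mammary tumor line oxidative phosphorylation (7.03e-04), cell cycle (0.00939, with Ccnd2 lower) and glycolysis genes (0.0284) fell, and glycolysis genes fell in the skin line (0.0206). The last 2 calls, that of cholesterol synthesis genes in the testis line and that of B and plasma cell genes in the kidney line ended against random lists (adjusted p = 0.0822, 0.230, 0.0645 and 0.173). On ranks the calls of interferon response genes in the myeloma line, pan-leukocyte genes in the myoblast line, glycolysis genes in the skin line and B and plasma cell genes in the kidney line ended (adjusted p = 0.0547, 0.0600, 0.0945 and 0.0801).

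Values above 3.46 numbered 13 on the T-cell lymphoma array, 9 on the myoblast array, 4 on the macrophage array and 3 on the embryo fibroblast array. In the liver line albumin (Alb) had a log2 ratio of 0.33 and was not called, like every gene there but Krt8.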
